A study of Nitrosopumilus zosterae with 6 samples.

How the data were processed

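Libraries came from Nitrosopumilus zosterae NM25 cultures of about 4 L, started with 1% of an 11-day inoculum. After 10 days, 3 L were filtered, the RNA on the filter was fixed, and total RNA was extracted and treated with DNase, per the labels' protocols. Libraries were made with a stranded total RNA kit that removes ribosomal RNA, per the labels' protocols. The trimming, aligner, counting tool, strand setting, genome build and annotation version are not given in the sources used here. No reference genome was used here, so reads shared between related genes, GC content and antisense counting could not be checked.

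The authors deposited a table of raw read counts per gene for all 6 libraries, with a locus tag, product name and coordinates for each of 2088 genes, and no ribosomal or transfer RNA gene among them. The counts were whole numbers that were not normalized. Coordinates are printed as that deposited table gives them, and it names neither sequence nor build. They reach 1775052, and 99.95% of lengths are multiples of 3, so lengths are coding lengths. The authors also deposited TPM values, scaled for gene length and library total, for each library. These TPM values were recomputed from the counts and coding lengths to within 2% for 100% of genes checked in each library, so they hold no information beyond the counts. A further deposited table gives the authors' own comparison, with a fold change, a log2 fold change, a p-value and an adjusted p-value per gene. Its signed fold change and largest group mean are scores as the authors deposited them, and the unit of the latter is not given in the sources used here. The test behind it is not given in the sources used here. The 40 genes with no value in that table are the 40 with 0 counts in all libraries. It has no samples of its own and is used only for description.

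Samples were grouped by the treatment in the labels, as 3 without and 3 with alpha-ketoglutarate. Before averaging, the 3 pairs of libraries in each group were compared by a chi-square test over genes with at least 10 counts in the pair. The chi-square per degree of freedom lay between 1.47 and 3.07, so no pair agreed within sampling noise and no library was a copy of another. Correlations of log CPM across genes, which are not independent replicates, lay between 0.967 and 0.977 within groups and between 0.794 and 0.831 across groups.

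Changes were tested on the deposited counts with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood test, two-sided, with TMM scaling and the low-count filter of edgeR, which kept 1385 genes and left 703 untested. The biological coefficient of variation was 10.1%. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene was called at 0.05. Log2 fold changes are without minus with alpha-ketoglutarate. Their SE comes from the spread of log CPM between the 3 libraries of each group. With 3 libraries this spread can lie below counting error, so a small SE alone does not make a fold certain. CPM values are scaled by the TMM factors, which ranged from 1.58 to 1.82 without and from 0.54 to 0.62 with alpha-ketoglutarate because of the dominant gene.

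Before the data were examined, 27 gene lists were fixed as word patterns on product names. The 26 with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The patterns also took in some products they were not meant for, and cleaned lists were added after seeing the data. The rule for named genes was fixed at the same time. Among called genes whose groups do not overlap and whose mean log2 CPM is at least 3, it takes the 8 largest changes in each direction with a known product and the 3 largest in each direction without one. It adds the 3 members that moved most in the direction of each called list, the ammonia monooxygenase genes, the 8 most abundant members of the peroxide and nitrogen lists, at most 2 examples of each other list, and the 5 most abundant features of each group. Some of the examples are left out of the text.

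Shares of counts carry Wilson 95% intervals. Comparisons of single values used exact permutation tests (SciPy 1.17.1), two-sided, where 3 against 3 cannot go below 0.1. The share of hypothetical proteins was tested with Fisher's exact test over tested genes. Adjacent changed genes were counted against all 1384 distinct circular shifts of the calls, which keep neighboring calls together, one-sided, where more shifts had been planned than exist.

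The steps were tested on simulated counts with 200 changed genes drawn from these libraries' means and sizes. Changes of 1.5-fold, 2-fold and 4-fold were found for 38.9%, 83.4% and 100% of the changed genes tested, in steps that ran on 1288, 1304 and 1274 genes, with 3.9%, 2.5% and 3.26% of calls false. As many simulated genes rose as fell, fewer changed than the 808 called in the real data, and the dominant gene did not change. These shares of false calls therefore do not test the effect of the dominant gene on scaling. A simulated shift of the ribosomal protein list was called, with 0 other lists called. Simulated genes were drawn independently of each other, so this does not test false list calls where members are correlated, as in the real lists. Alternatives covered other scalings, DESeq2 1.42.0, other count filters, limma on log2(TPM + 1) with a filter at 10 TPM in at least 3 libraries, a pseudocount of 0.1, no TPM filter, a stricter threshold, the replicate number as a block, and each library left out in turn.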

Results

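RNA was sequenced from cultures of Nitrosopumilus zosterae strain NM25, a marine archaeon that lives by oxidizing ammonia to nitrite. The cultures were sampled after 10 days at 30 degrees Celsius in the dark in medium with 1 mM ammonium chloride. Alpha-ketoglutarate, a keto acid that removes hydrogen peroxide by reacting with it, stood at 1 µM at the start in the cultures to which none was added. In the other cultures it was added to 100 µM. Each group had 3 libraries. The count tables covered 2088 protein-coding genes, of which 718 carried the product name hypothetical protein.

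Total counts were 255055, 335817 and 362798 in the libraries without alpha-ketoglutarate and 994538, 656322 and 958192 in those with it. The group means were 317890 ± 56064 (SD, n = 3) and 869684 ± 185668 (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). One gene made up most of this gap. OO712_RS01205 (hypothetical protein, plus strand, 202835 to 208003, coding length 5169 bp) held 35.4% ± 2.46 (SD, n = 3) of the counts without and 74.2% ± 0.334 (SD, n = 3) with alpha-ketoglutarate (exact permutation test, two-sided, p = 0.1). The single libraries lay at 34.4% (Wilson 95% interval 34.2 to 34.5), 38.2% (38.0 to 38.3) and 33.6% (33.4 to 33.8) without. With alpha-ketoglutarate they lay at 74.6% (74.5 to 74.7), 74.2% (74.1 to 74.3) and 73.9% (73.8 to 74.0). These intervals cover counting error only. Counts outside this gene averaged 205323 ± 36788 (SD, n = 3) without and 223953 ± 47453 (SD, n = 3) with (exact permutation test, two-sided, p = 0.5). The median gene had between 12 and 19 counts per library.

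**Figure D1:**
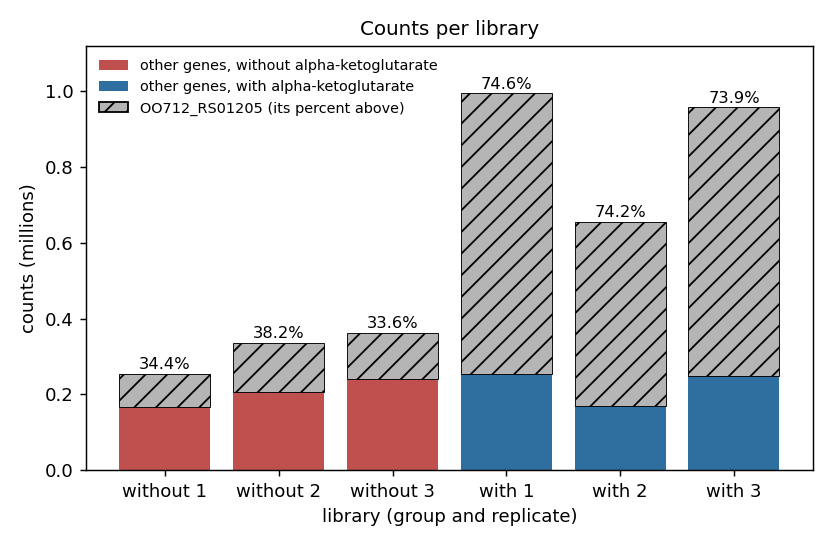
Counts per library (vertical axis), split into the gene OO712_RS01205 (hatched, its percent of the library printed above) and all other genes (solid, colored by group). The gene held 33.6 to 38.2% of the counts in the 3 libraries without alpha-ketoglutarate and 73.9 to 74.6% in the 3 with it.

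The comparison asked how gene expression differs between cultures left without the hydrogen peroxide scavenger and cultures given it. Fold changes are for without against with alpha-ketoglutarate. Among genes with a named product that met the rule for named genes, 2 cell division genes, OO712_RS06340 and OO712_RS10365, fell most without alpha-ketoglutarate. The CdvA-like protein OO712_RS06340, of the archaeal division machinery, had a log2 fold change of -4.70 ± 0.39 (SE, n = 3 per group, adjusted p = 3.18e-09), from 2668 ± 93.8 to 102 ± 51.7 CPM (SD). All 10 tested genes of the NADH dehydrogenase complex, which lie close together on the genome, and 36 of 50 ribosomal protein genes fell as well. Of DNA repair genes 8 of 14 rose, of iron-sulfur cluster and iron genes 6 of 10, and of general transcription factors 8 of 12, while 2 of the latter fell. None of the 9 calls of lists as sets held with an estimated correlation (adjusted p = 0.233 to 0.337 with an estimated correlation). With a stricter count filter, the NADH dehydrogenase, ribosomal protein and motility lists were called and the other 6 were not (camera adjusted p = 0.0819 to 0.182). The small heat shock protein OO712_RS10645 (Hsp20 family) rose by a log2 fold change of 3.50 ± 0.16 (SE, n = 3 per group, adjusted p = 2.89e-29).

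In all, 808 of 1385 tested genes (58.3%) changed, 405 upward and 403 downward, and 434 of them changed at least 2-fold (244 up, 190 down). A change of at least 4-fold was found for 115 genes (73 up, 42 down). All 3 values of one group lay above all 3 of the other for 858 tested genes (61.9%), where chance gives 10%, and 762 of these were among the changed genes. On scales that count the dominant gene differently, the log2 folds of all tested genes moved together: the median shift was 1.54 on library size alone, 0.16 with upper-quartile factors, 0.55 in the TPM values and 0.21 on library size without OO712_RS01205. The split into higher and lower genes followed, with 1196 and 44 on library size alone, 482 and 320 with upper-quartile factors, 659 and 174 on TPM, and 501 and 293 on library size without OO712_RS01205. Every list median below 0 given here turned upward on library size alone except those of the NADH dehydrogenase and motility lists, and on TPM all but these and the ribosomal protein, ATP synthase and ammonium uptake lists. Directions are therefore relative to the tested genes as a whole, as TMM scaling sets them. Of the 75 changed genes named here, 13 turned upward on library size alone and 0 turned under the 4 other scalings (DESeq2 size factors, upper-quartile factors, TPM and library size without OO712_RS01205).

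**Figure D2:**
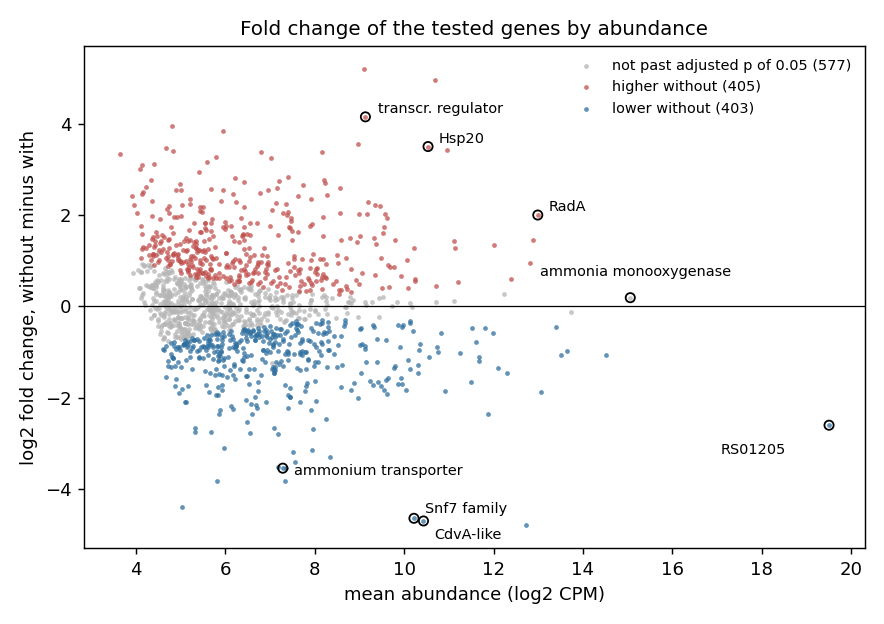
Log2 fold change (without minus with alpha-ketoglutarate, vertical axis) of the 1385 tested genes against their mean abundance (horizontal axis, log2 CPM), 3 libraries per group, on the TMM scale. Colors mark the 405 genes higher and 403 lower at an adjusted p of 0.05, and circles mark genes named in the text, with OO712_RS01205 far to the right at -2.60. On library size alone all points would move up by a median of 1.54, and genes between -1.54 and 0 would turn upward.

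Cell division, replication and chromatin genes stood below other genes (19 tested, 2 rose, 9 fell, 8 not called, 10 fell when adjusted over the list alone; median log2 fold -0.31, 1.23 on library size alone and 0.24 on TPM; camera adjusted p = 0.00303). The set call did not hold with an estimated correlation (adjusted p = 0.233 with an estimated correlation). Beside the CdvA-like gene, Snf7 family genes, whose products form the contractile filaments of division in these archaea, fell: OO712_RS10365 by a log2 fold of -4.64 ± 0.27 (SE, adjusted p = 6.19e-33) and OO712_RS05670 by -2.24 ± 0.11 (SE, adjusted p = 1.05e-11). Motility and chemotaxis genes also stood lower (9 tested, 1 rose, 7 fell, 1 not called, 7 fell when adjusted over the list alone; median -1.77; camera adjusted p = 0.00344, adjusted p = 0.233 with an estimated correlation). Flagellin genes OO712_RS03830, OO712_RS03850 and OO712_RS03840, for the archaeal swimming filament, fell by log2 folds of -2.01, -1.95 and -1.87. Flagellin and Snf7 genes come in several copies, and counts of reads shared between copies are uncertain.

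All 10 tested NADH dehydrogenase genes, named as NADH-quinone oxidoreductase subunits, were lower (10 fell when adjusted over the list alone; median log2 fold -2.18, and -0.64 on library size alone; camera adjusted p = 2.97e-09, adjusted p = 0.233 with an estimated correlation). They lie close together, between 1457254 and 1467638. They may be transcribed together and need not be 10 independent cases. Subunits M (OO712_RS08900), L (OO712_RS08895) and N (OO712_RS08890) had log2 folds of -3.54 ± 0.20, -3.29 ± 0.13 and -2.69 ± 0.16 (SE). The last of these overlaps a gene on the other strand by 11 bp. Of 8 tested ATP synthase genes, 5 fell and 3 were not called (5 fell when adjusted over the list alone; median -0.90, which turns to 0.65 on library size alone; camera adjusted p = 0.0192, adjusted p = 0.337 with an estimated correlation). The set call was lost on library size alone (camera adjusted p = 0.322). A secretion ATPase taken in by the list was among those not called. V-type subunits D (OO712_RS00610), B (OO712_RS00605) and E (OO712_RS00595) had log2 folds of -1.86, -1.61 and -1.0. These subunits belong to a run of 4 adjacent genes that all fell (99928 to 104326), so they may not be independent cases. Among cytochromes and the terminal oxidase, 3 of 5 fell and 1 rose (3 and 1 when adjusted over the list alone; median -0.40, 1.16 on library size alone and 0.16 on TPM; camera adjusted p = 0.107), with the oxidase subunit OO712_RS09675 at -1.69 ± 0.13 and cytochrome b OO712_RS01225 at -1.58 ± 0.06 (SE). Among 15 blue copper electron carriers, small proteins thought to shuttle electrons in these archaea, 6 fell and 1 rose (6 and 1 when adjusted over the list alone; median -0.13, 1.42 on library size alone and 0.36 on TPM; camera adjusted p = 0.107). Plastocyanin family genes OO712_RS09670 and OO712_RS02795 had log2 folds of -2.46 and -1.22.

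Ribosomal protein genes fell in 36 of 50 cases, none rose and 14 were not called (36 fell and 1 rose when adjusted over the list alone; median log2 fold -0.80, which turns to 0.74 on library size alone). Their camera adjusted p was 0.000303, and the adjusted p = 0.337 with an estimated correlation. Examples were 50S proteins L31e (OO712_RS02695) at -2.11 ± 0.19, L39e (OO712_RS02690) at -2.09 ± 0.46 and L14 (OO712_RS05750) at -1.50 ± 0.15 (SE). The L39e gene passed the count filter only while the libraries of replicates 1 and 2 with alpha-ketoglutarate were both kept. Of 29 translation factors and aminoacyl-tRNA synthetases, 16 fell and 2 rose (16 and 2 when adjusted over the list alone; median -0.47, 1.09 on library size alone and 0.09 on TPM), but the set was not called (camera adjusted p = 0.088). Elongation factor EF-2 (OO712_RS06050), which moves the ribosome along its message, fell by a log2 fold of -1.71 ± 0.09 (SE), and phenylalanine--tRNA ligase subunit alpha (OO712_RS01530) by -1.72 ± 0.43 (SE). In the RNA polymerase list, 2 of 9 rose and 2 fell (0 and 2 when adjusted over the list alone), with subunit A' (OO712_RS08580) at -1.28 ± 0.05 (SE). Its median was 0.04, its mean -0.11 and its camera direction downward (adjusted p = 0.761).

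Ammonium uptake and nitrogen assimilation genes stood lower (6 tested, 1 rose, 4 fell, 1 not called, 4 fell when adjusted over the list alone; median -1.0, which turns to 0.55 on library size alone). Their camera adjusted p was 0.0387 (adjusted p = 0.337 with an estimated correlation), and the call was lost on library size alone (adjusted p = 0.159) and without replicate 1 of the group with alpha-ketoglutarate (adjusted p = 0.0531). The ammonium transporter genes OO712_RS07105 and OO712_RS00575 fell by log2 folds of -3.55 ± 0.12 and -1.87 ± 0.20 (SE), the former from 284 ± 15.4 to 24.2 ± 3.78 CPM (SD, n = 3). Glutamate dehydrogenase family gene OO712_RS02455, which joins ammonium to a keto acid, fell by -0.89 ± 0.01 (SE). Of the P-II regulators, which sense nitrogen state, OO712_RS02430 rose by 1.44 ± 0.23, OO712_RS01330 fell by -1.10 ± 0.18 and OO712_RS07115 had -0.49 ± 0.06 (SE, adjusted p = 0.171). OO712_RS07115 had 11, 14 and 15 counts without and 21, 15 and 17 with alpha-ketoglutarate, so its fold is less certain than its SE shows. The SE of OO712_RS02455 may also understate the uncertainty of its fold.

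Genes of ammonia oxidation went both ways (7 tested, 3 rose, 3 fell, 1 not called, the same counts adjusted over the list alone; camera adjusted p = 0.705). Of 3 genes annotated as ammonia monooxygenase, the enzyme of the first oxidation step, OO712_RS01435 and OO712_RS01450 fell by log2 folds of -1.08 ± 0.15 and -0.97 ± 0.17 (SE), with 0.46 and 0.58 on library size alone. OO712_RS01440, among the most abundant transcripts at 36327 ± 3848 CPM without and 31873 ± 6932 CPM with (SD, n = 3), had a log2 fold of 0.19 ± 0.19 (SE, adjusted p = 0.324). It became 0.37 (adjusted p = 0.0124) without replicate 3 of the group with alpha-ketoglutarate. It was also called higher with upper-quartile factors (0.36), the stricter filter (0.34), TPM (0.76), library size alone (1.74) and library size without OO712_RS01205 (0.41). Of the 4 multicopper oxidase genes of the list, OO712_RS02730 fell, at -1.07 ± 0.17, and 3 rose: OO712_RS08255 at 1.35 ± 0.07, OO712_RS02050 at 2.66 ± 0.17 and OO712_RS03045 at 0.61 ± 0.12 (SE). The last of these was named after its values were seen. The PEFG-CTERM protein gene OO712_RS00675, also among the 5 most abundant features without alpha-ketoglutarate, had -0.12 ± 0.15 (SE, adjusted p = 0.49).

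Peroxide and redox defence genes rose in 13 of 28 tested cases, 5 fell and 10 were not called (13 and 5 when adjusted over the list alone), and the list as a set was not called (median 0.35; camera adjusted p = 0.155, adjusted p = 0.473 with an estimated correlation). On library size alone it was called higher at the preset correlation (camera adjusted p = 0.0333). The 13 genes that rose had log2 folds from 0.39 to 1.56, and the 5 that fell from -1.77 to -0.52. The members of this list named here were taken by abundance, and none of the 5 that fell is among them. Peptide-methionine sulfoxide reductase MsrA (OO712_RS04435), which repairs oxidized methionine, rose by a log2 fold of 1.5 ± 0.12 (SE, adjusted p = 1.3e-15). Thioredoxin OO712_RS09465 rose by 0.39 ± 0.22 (SE, adjusted p = 0.0126), a call lost without replicate 2 (0.28, adjusted p = 0.0938) or 3 (0.28, adjusted p = 0.131) of the group without alpha-ketoglutarate. The redoxin domain gene OO712_RS02770 rose by 0.48 ± 0.15 (SE), lost without replicate 2 of that group (0.37, adjusted p = 0.051). Superoxide dismutase OO712_RS08330, which turns superoxide into hydrogen peroxide, had 0.28 ± 0.17 (SE, adjusted p = 0.0714). It passed at 0.31 (adjusted p = 0.0205) without replicate 1 of the group without, and at 0.44 (adjusted p = 0.00108) without replicate 3 of the group with alpha-ketoglutarate. It was also called higher with upper-quartile factors (0.45), the stricter filter (0.43), no filter (0.31), TPM (0.85), library size alone (1.83) and library size without OO712_RS01205 (0.50). The list also took in ferredoxins, which carry electrons. OO712_RS09195, OO712_RS08000 and OO712_RS07710 rose by 0.59, 1.07 and 0.86, and OO712_RS09200 had -0.25 (adjusted p = 0.0768, and -0.33 with adjusted p = 0.0334 without replicate 2 of the group with alpha-ketoglutarate). With ferredoxins and cupredoxins left out, a choice made after seeing the data, 9 of 18 rose and 3 fell.

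Iron-sulfur cluster assembly and iron genes rose in 6 of 10 cases and none fell (6 rose when adjusted over the list alone; median 0.65; camera adjusted p = 0.0387, adjusted p = 0.337 with an estimated correlation). Scaffold proteins SufB (OO712_RS07720) and SufD (OO712_RS07715) rose by log2 folds of 1.44 ± 0.05 and 1.28 ± 0.07, and the metal-dependent regulator OO712_RS10030 by 1.52 ± 0.54 (SE). The regulator had 9, 1 and 3 counts in the libraries with alpha-ketoglutarate, and its fold was 2.45 without replicate 1 of that group. The set call was lost without replicate 2 of the group with alpha-ketoglutarate (adjusted p = 0.0646). DNA repair and recombination genes rose in 8 of 14 cases and none fell (8 rose when adjusted over the list alone; median 0.69; camera adjusted p = 0.0444, adjusted p = 0.337 with an estimated correlation). The recombinase RadA (OO712_RS01990), which pairs DNA strands, rose by 2.00 ± 0.06 (SE, adjusted p = 1.99e-18), from 3249 ± 155 to 12994 ± 787 CPM (SD, n = 3). Resolvase OO712_RS05550 and the integrase or transposase gene OO712_RS01975, which acts on mobile DNA rather than repair, rose by 1.92 and 1.60. With products taken in by chance left out, a choice made after seeing the data, 7 of 11 rose and none fell. The repair set was not called without replicates 2 or 3 of the group without (adjusted p = 0.0805 and 0.0523), nor without replicates 1 or 2 of the group with alpha-ketoglutarate (adjusted p = 0.0523 and 0.0846).

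**Figure D3:**
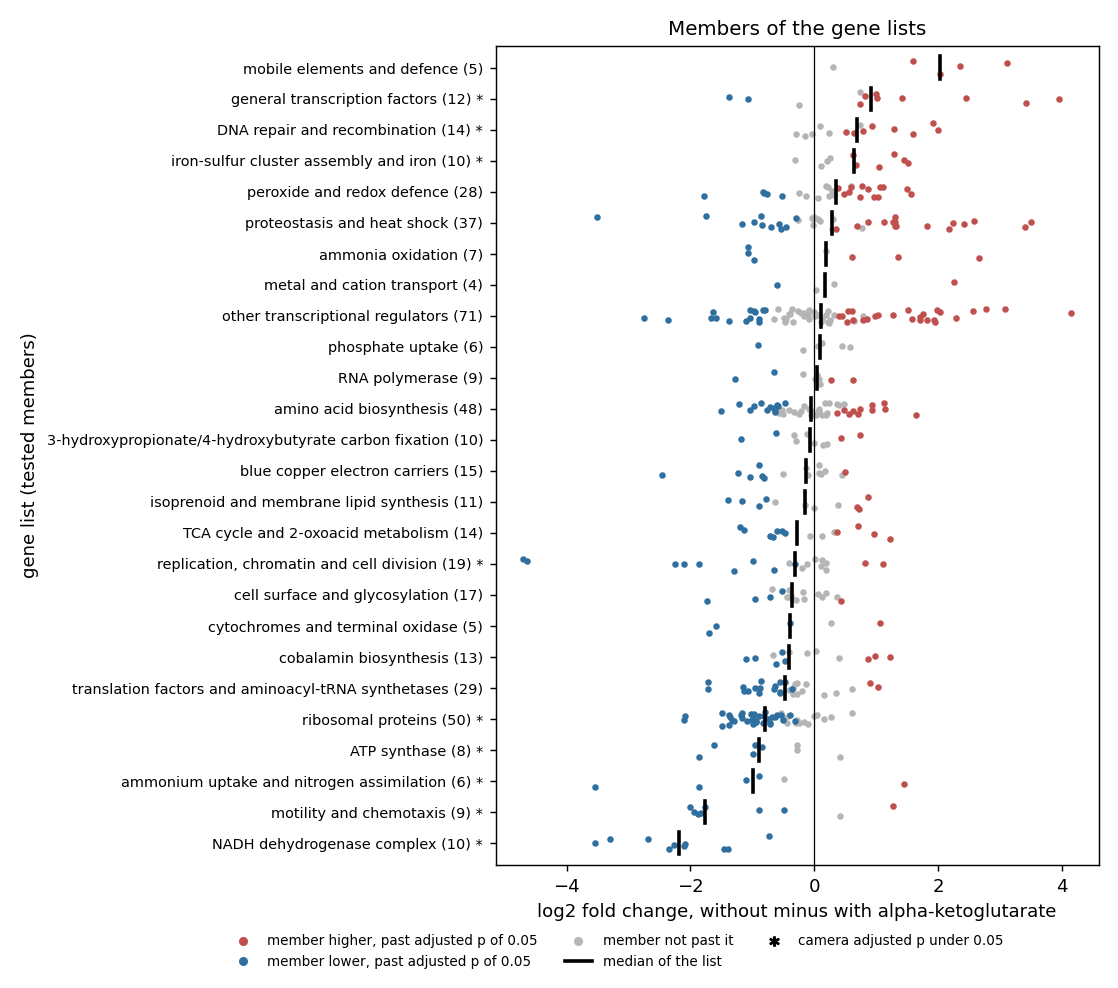
Log2 fold change (without minus with alpha-ketoglutarate, horizontal axis, TMM scale) of every tested member of 26 gene lists (vertical axis, number of tested members in brackets). Points are genes, black bars are list medians and stars mark lists with a camera adjusted p under 0.05, from the NADH dehydrogenase complex at a median of -2.18 to general transcription factors at 0.91. On library size alone all points would move up by a median of 1.54, which turns every negative median upward except those of the NADH dehydrogenase and motility lists.

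General transcription factors rose in 8 of 12 cases and 2 fell (8 and 2 when adjusted over the list alone; median 0.91; camera adjusted p = 0.019, adjusted p = 0.337 with an estimated correlation). The factors IIB OO712_RS07895 and OO712_RS04590, which recruit RNA polymerase to promoters, rose by log2 folds of 3.96 ± 0.38 and 2.46 ± 0.23, and OO712_RS10625, annotated as TFIIIB, by 3.42 ± 0.11 (SE). OO712_RS07895 had 3, 0 and 1 counts in the libraries with alpha-ketoglutarate, and its fold was 5.06 without replicate 1 of that group. Counts of reads shared among these related genes are uncertain. Among 71 other transcriptional regulators, 26 rose and 15 fell (the same counts adjusted over the list alone; camera adjusted p = 0.352). On the TMM scale with all libraries, OO712_RS02985 had the largest rise among genes with a named product that met the rule for named genes. Its log2 fold was 4.15 ± 0.08 (SE, adjusted p = 1.79e-31), from 59.3 ± 4.42 to 1050 ± 75.6 CPM (SD, n = 3). The small regulator OO712_RS01325, with an Lrp/AsnC ligand binding domain, rose by 2.03 ± 0.16 (SE).

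Proteostasis and heat shock genes went both ways (37 tested, 16 rose, 11 fell, 10 not called, the same counts adjusted over the list alone; camera adjusted p = 0.155). Of 6 tested genes in the list named only AAA family ATPase, 4 fell and 0 rose. Of 11 named universal stress protein, 5 rose and 4 fell. Next to the Hsp20 gene, the CDC48 family gene OO712_RS10640, for an unfolding ATPase, rose by 2.59 ± 0.17 (SE). The universal stress protein OO712_RS09540 rose by 3.40 ± 0.27, while the AAA family ATPase OO712_RS03995 fell by -3.51 ± 0.16 (SE). OO712_RS09540 had 2, 1 and 3 counts in the libraries with alpha-ketoglutarate, so the size of its fold is uncertain. In the list of osmolytes and mechanosensitive channels, with 2 tested genes, 1 rose (1 when adjusted over the list alone) and no set test was run. It was the channel OO712_RS04540, of a family that opens under membrane tension, at 3.38 ± 0.16 (SE). Mobile element and defence genes rose in 4 of 5 cases (4 when adjusted over the list alone; camera adjusted p = 0.125), with the HicB antitoxin OO712_RS02875 at 3.12 ± 0.56 and the RelE/ParE toxin OO712_RS02245 at 2.36 ± 0.24 (SE). The size of the HicB fold is uncertain, with 0, 2 and 3 counts in the libraries with alpha-ketoglutarate. Relative to the common shift it was 4.03 on TPM, with a TPM pseudocount of 0.1 (5.71) it was not called, and it was 2.43 without replicate 1 and 3.77 without replicate 3 of that group. The SMC family ATPase OO712_RS02810, of a family that shapes chromosomes, rose by 3.55 ± 0.15 (SE). In the other direction stood the PRC-barrel gene OO712_RS07830 at -3.82 ± 0.13 and the Ig domain gene OO712_RS09305 at -2.78 ± 0.19 (SE).

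**Figure D4:**
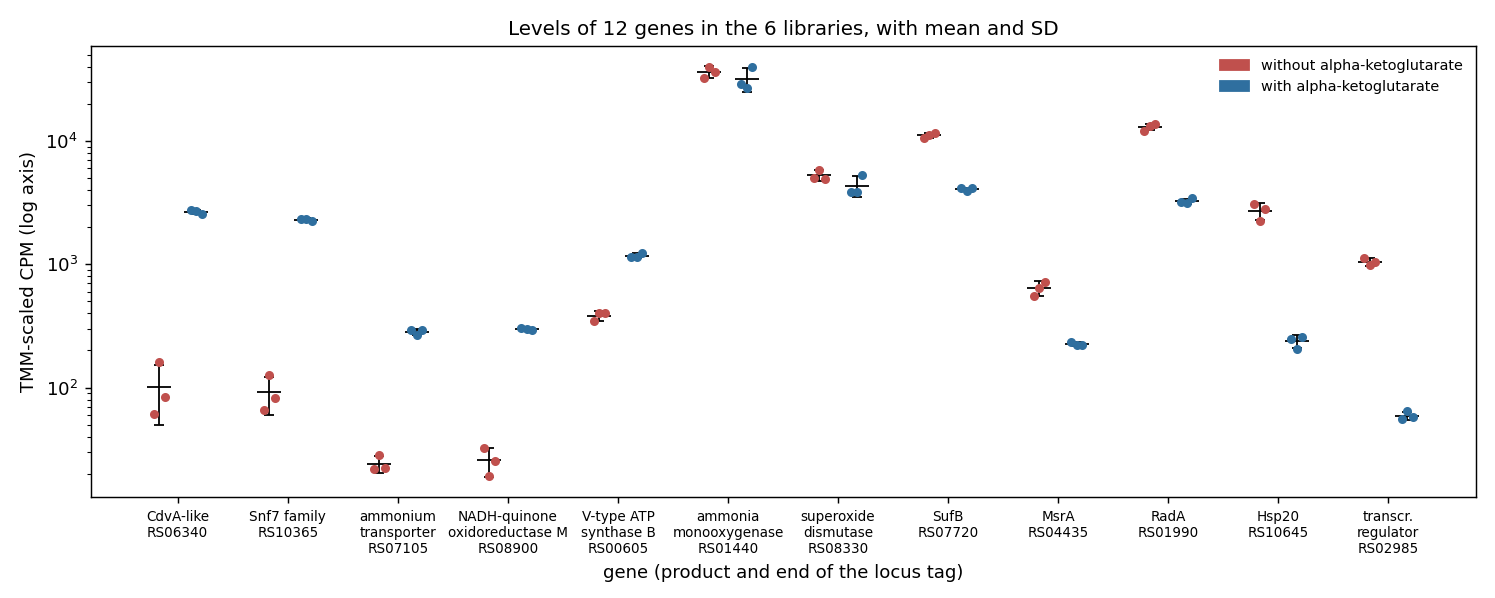
TMM-scaled CPM (vertical log axis) of 12 genes in the 3 libraries without (red) and the 3 with alpha-ketoglutarate (blue), with the mean and SD of each group in black. The groups do not overlap for the CdvA-like, Snf7, ammonium transporter, NADH dehydrogenase, ATP synthase, SufB, MsrA, RadA, Hsp20 and regulator genes, while they do for OO712_RS01440 and superoxide dismutase. The ATP synthase subunit B gene, at a log2 fold of -1.61, is at -0.07 on library size alone.

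Several lists showed no call as a set. In carbon fixation by the 3-hydroxypropionate/4-hydroxybutyrate cycle, 2 of 10 genes rose and 2 fell (2 and 2 when adjusted over the list alone; camera adjusted p = 0.813), with 4-hydroxybutyryl-CoA dehydratase OO712_RS09485 at 0.73 and enoyl-CoA hydratase OO712_RS02545 at -1.18. In the TCA cycle and keto acid list, 4 of 14 rose and 7 fell (4 and 7 when adjusted over the list alone; camera adjusted p = 0.813), with succinate dehydrogenase genes OO712_RS09085 at 0.71 and OO712_RS09095 at -1.20. Amino acid biosynthesis had 11 of 48 up and 13 down (the same counts adjusted over the list alone; camera adjusted p = 0.813), including cysteine synthase OO712_RS06770 at 1.13 and threonine synthase OO712_RS01195 at -1.04. Cobalamin biosynthesis had 3 of 13 up and 5 down (3 and 5 when adjusted over the list alone, camera adjusted p = 0.705). With products taken in by chance left out, a choice made after seeing the data, 3 of 11 were up and 3 down (median -0.12 after -0.42). Isoprenoid synthesis had 3 of 11 up and 4 down (4 and 4 when adjusted over the list alone; camera adjusted p = 0.705). Cell surface genes had 1 of 17 up and 4 down (1 and 4 when adjusted over the list alone; camera adjusted p = 0.543). Phosphate uptake had 1 of 6 down, OO712_RS03070 at -0.91 (1 when adjusted over the list alone; camera adjusted p = 0.952, with a median of 0.09 against a downward test). Metal transport had 1 of 4 up, the cation transporter OO712_RS02055 at 2.25, and 1 down (1 and 1 when adjusted over the list alone; camera adjusted p = 0.516).

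Genes without a known function were among the largest changes. Hypothetical proteins OO712_RS06160, OO712_RS02980 and OO712_RS08415 rose by log2 folds of 5.20 ± 0.16, 4.96 ± 0.24 and 3.83 ± 0.65 (SE), and OO712_RS09425, OO712_RS00320 and OO712_RS06195 fell by -4.80 ± 0.29, -4.39 ± 0.21 and -3.82 ± 0.12 (SE). OO712_RS08415 had 6, 0 and 5 counts in the libraries with alpha-ketoglutarate, so the size of its fold is uncertain: relative to the common shift it was 5.15 on TPM, and with a TPM pseudocount of 0.1 (6.82) it was not called. In the libraries without alpha-ketoglutarate, OO712_RS00320 had 2, 1 and 1 counts and OO712_RS06195 had 3, 4 and 4. The sizes of these 2 folds are therefore less certain than their SE shows. OO712_RS00320 passed the count filter only while the libraries of replicates 1 and 2 with alpha-ketoglutarate were both kept. The dominant gene OO712_RS01205 fell by -2.60 ± 0.13 (SE, adjusted p = 3.19e-16). Hypothetical proteins made up 25.7% of the 808 changed genes and 21.3% of the 577 others (Fisher's exact test, two-sided, odds ratio 1.28, p = 0.0638). The difference passed the same exact test with changes of at least 2-fold (31.1% of 434 against 20.6% of 951, odds ratio 1.74, p = 3.25e-05) and at an adjusted p of 0.01 (odds ratio 1.30, p = 0.0373). By direction, hypothetical proteins made up 31.6% of the 405 genes that rose against 20.7% of the others (odds ratio 1.77, Fisher's exact test, p = 2.28e-05), but 19.9% of the 403 that fell against 25.6% of the others (odds ratio 0.72, p = 0.0263). These tests take genes as independent, though adjacent genes may change together. The split by direction also depends on the scaling.

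In 30.4% of 629 pairs of adjacent genes on the same strand both genes changed in the same direction, against a mean of 26.1% over all 1384 circular shifts of the calls along the genome (one-sided permutation test over shifts, p = 0.00144). The shifts keep neighboring calls together, so they set pairs on the same strand against adjacent genes in general and do not test whether neighbors change together. The 808 changed genes formed 617 loci. In the authors' deposited table, 833 of 2048 genes with a value were called at the same threshold, 411 higher and 422 lower. Of 808 genes called here, 771 (95.4%) were called in the authors' deposited table, all 771 with the same sign. Both start from the same counts, so this is a comparison of methods.

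At these depths simulated changes of 2-fold were found for 83.4% of genes and of 1.5-fold for 38.9%, so a smaller change in a gene not called was often not detectable at this depth. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.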

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

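The scaling without the most abundant gene, the removal of the length trend and the cleaned lists were chosen after seeing the data, and all other settings before. Counts of genes changed stayed within 1.5 times of 808 under every setting but library size alone (1240, with 1196 higher, 44 lower and 1021 at least 2-fold) and the stricter filter (430, with 211 higher, 219 lower and 210 at least 2-fold). The stricter filter tested only 547 genes. On TPM values 659 were higher and 174 lower (633 and 174 with a pseudocount of 0.1, 648 and 174 without a filter). DESeq2 called 604 genes. Library size alone counts the dominant gene in full, which shifts all genes by a median of 1.54. Leaving out each library in turn gave 713 to 798 changed genes, 347 to 391 higher, 366 to 411 lower, 411 to 489 at least 2-fold and 7 to 10 lists. Of the 808 calls, 594 held in all 6 such fits and 0 changed sign. Of 26 lists tested, 9 were called with camera, 3 with the stricter filter, 0 with an estimated correlation and 20 with fry, which does not compare a list with other genes. The odds ratio of hypothetical proteins passed at 1.30 with an adjusted p of 0.01 and at 1.74 for changes of at least 2-fold, and the cause was not tested. Pairs within 100 bp of each other changed in the same direction in 28.9% of 498 cases (permutation test over shifts, p = 0.0491).

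Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.07 to 0.00. With the replicate number as a block, 791 genes changed (393 higher, 398 lower), 432 at least 2-fold. The planned fits with protein-coding genes only or with ribosomal RNA kept gave no value, since the count table lists only protein-coding genes.

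On library size alone these log2 folds turned upward through the common shift: OO712_RS01330 0.44, OO712_RS05750 0.049, OO712_RS00595 0.55, OO712_RS01435 0.46, OO712_RS01450 0.58, OO712_RS09200 1.30, OO712_RS02455 0.66, OO712_RS07115 1.04, OO712_RS02795 0.33, OO712_RS02545 0.37, OO712_RS09095 0.35, OO712_RS08580 0.27, OO712_RS03070 0.63, OO712_RS01195 0.50, OO712_RS02730 0.49 and OO712_RS00675 1.44. On TPM, OO712_RS09200 was at 0.32 under all 3 TPM settings and OO712_RS07115 at 0.052 (0.053 with a pseudocount of 0.1). OO712_RS00675, near 0, was at 0.44 on TPM, 0.043 with upper-quartile factors, 0.027 with the stricter filter, 0.10 on library size without the most abundant gene, and between -0.21 and 0.023 with each library left out in turn, the latter without replicate 3 of the group with alpha-ketoglutarate. Among named genes, calls were lost with the direction kept for 8 on library size alone, for 4 under all 3 TPM settings (OO712_RS01330, OO712_RS00595, OO712_RS09095 and OO712_RS03070), for 2 more with a TPM pseudocount of 0.1 (OO712_RS02875 and OO712_RS08415) and for OO712_RS09465 with DESeq2. Depth was low, with 12 to 19 counts for the median gene, and its part in these changes of calls was not tested.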

Other observations

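The expected outcomes of all tests of explanations in this part, the counts of splits included, were written after the results were seen, and the groups of genes by shared product name were formed after seeing the data. Among product names shared by at least 5 tested genes, 4 stood apart in camera. Genes with an Lrp/AsnC ligand binding domain, found in regulators that sense amino acids, rose in 5 of 7 cases and none fell (median log2 fold 1.71, adjusted p = 0.0484). Transcription initiation factor IIB genes rose in 6 of 8 cases and none fell (median 1.01, adjusted p = 0.0334). Flagellin genes fell in 5 of 6 cases and 1 rose (median -1.85, adjusted p = 0.00218), and PEFG-CTERM proteins, exported proteins with a sorting signal, fell in 4 of 8 and 1 rose (median -0.77, adjusted p = 0.0334). The flagellin genes also belong to the motility list and the factor IIB genes to the general transcription factor list, so these groups partly repeat those calls. For all 4 groups the adjusted p = 0.494 with an estimated correlation. On library size alone every median moves up by about 1.54, which turns that of the PEFG-CTERM proteins.

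Changed genes also formed 10 runs of at least 4 neighbors on one strand that moved together, 50 genes in all. Runs of 7 held NADH dehydrogenase subunits (1462672 to 1467638, median log2 fold -2.08) and ribosomal proteins with the SecY translocase subunit (1352263 to 1356992, median -0.99). A run of 6 held lysine and arginine synthesis genes (432529 to 438131, median -0.70). Runs of 5 held a terminal oxidase with its plastocyanin (1586888 to 1590578, median -1.69) and a nitroreductase with agmatinase and an aldehyde dehydrogenase (363347 to 367893, median 1.14). Runs of 4 included the DnaJ, DnaK and GrpE chaperones (1667842 to 1671949, median 1.13) and the Suf iron-sulfur genes (1258168 to 1262535, median 1.07). Hypothetical proteins made up 41.1% of the 73 genes that rose at least 4-fold (Fisher's exact test, odds ratio 2.34, p = 0.000988) and 28.6% of the 42 that fell at least 4-fold (odds ratio 1.28, p = 0.465). Here too the test takes genes as independent, and the direction depends on the scaling.

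The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. For each of the 5 counts, 1 of the 10 splits, the real one, gave a count as large: 808 genes changed, 405 higher, 403 lower and 434 at least 2-fold, with 0 as the highest of the other splits each time. For gene lists the real value was 9 and the highest of the other splits 4. Each of the other splits called at least 1 list while calling 0 genes. Camera at the preset correlation can therefore call lists where no gene is called.

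OO712_RS01205 took 35.4% of counts without and 74.2% with alpha-ketoglutarate. Loss of long transcripts without alpha-ketoglutarate would lower other long genes about as much, but the 138 others among the longest genes (at least 1586 bp) had a median log2 fold of -0.31 (95% bootstrap interval -0.48 to -0.11) against -2.60. This value argues against an equal loss of all genes of at least 1586 bp as the whole cause. OO712_RS01205 has 5169 bp, so a loss that keeps growing with length beyond 1586 bp was not tested and stays open. The difference in alpha-ketoglutarate itself, which the design names, and reads shared with similar sequences were not tested for this gene and stay open.

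Of 6 growth-linked lists, the NADH dehydrogenase, ribosomal protein, ATP synthase and replication, chromatin and cell division lists were called lower. In the last of these, the CdvA-like and 2 Snf7 genes had log2 folds of -4.70, -4.64 and -2.24. Its median over 19 genes was -0.31, and 2 of them rose. Translation factors (camera adjusted p = 0.088) and RNA polymerase (0.761, 2 rose and 2 fell) were not called. The repair, iron-sulfur and transcription factor lists were called higher, and no list call held with an estimated correlation (adjusted p = 0.233 to 0.337 with an estimated correlation). A gene length trend is argued against as the whole cause, since 8 of the 9 called lists kept their direction past the threshold once it was removed. The iron-sulfur list, at a median of 0.53 after 0.65, missed the threshold (camera adjusted p = 0.0501). That value came from camera on per-gene test statistics and the 0.0387 given above from camera on counts, so the 2 are not directly comparable. Another growth rate or stage without alpha-ketoglutarate could give these list calls, and 5 of 6 growth-linked lists had medians below that of all tested genes. These 6 lists were grouped as growth-linked after the results were seen and include the lists called lower, so this count does not test growth. No culture density is given, and the count cannot separate growth from hydrogen peroxide either. A direct response to hydrogen peroxide may also contribute, but the peroxide and redox defence list decided nothing (adjusted p = 0.473 with an estimated correlation, with a call at the preset correlation on library size alone). Growth and hydrogen peroxide therefore cannot be told apart here. The difference in alpha-ketoglutarate itself, which the design names, was not tested for these lists and stays open too.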
